A study of Escherichia coli K-12 and Escherichia coli str. K-12 substr. MG1655 with 24 samples.

How the data were processed

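RNA-Seq had been run on 24 libraries of E. coli K-12 MG1655, from WT, Δnac and ΔntrC on ammonia, glutamine, cytidine and cytosine, with 2 libraries in each of 12 groups. Per the labels' protocols, cells were grown aerobically and RNA was stabilised with RNAprotect and extracted with RNeasy Plus kits. It was quantified by NanoDrop for WT and by Qubit for the deletion strains. Groups and replicate numbers came from the sample titles. The deposited table held 1 column per library, and its values were read as TPM because each column summed to 1e+06 and its values depended on gene length. The submitters' processing notes name Bowtie 1.0.0 and DESeq2, with no role or order. The genome build, annotation and read counter were not given in the sources used here, so it is unknown whether reads were assigned by strand.

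The table listed 4342 genes, of which 4248 matched a locus tag in a RefSeq gene table of assembly ASM584v2, and 94 did not. This table was used for names and lengths only, and no coordinates are given. Of the matched genes 4119 were protein coding, 79 pseudogenes and 50 noncoding RNAs, and 0 rRNA or tRNA genes were listed. TPM multiplied by reference length plus 1 came in whole multiples of 1 step per library for 97.4 to 98.1% of nonzero values, within a tolerance of 0.01 of a step. Reads recovered from these steps came to 2.27 to 6.31 M per library. They were used for depth, floors and counting intervals, which cover counting error only.

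TPM, as deposited, was converted to log2(TPM + 1), a scale that understates the change of low genes. The filter was a mean of at least 1 TPM over all libraries, which kept 4057 genes and left out 285. A model of 12 group means was fitted with limma 3.58.1 (trend and robust options) in R 4.3.3, with 12 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 28 comparisons. The comparisons were each source against ammonia in each strain, cytosine against cytidine in WT, the strains against each other on each source, and the differences between the deletion strains' and WT responses. The 20 gene lists were tested with camera at a preset correlation of 0.01. P-values were adjusted over 560 tests, of which 335 passed and 124 also did with an estimated correlation.

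Tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 5 highest and 5 lowest called genes of each WT comparison with ammonia, and 3 and 3 elsewhere, where the libraries of both groups did not overlap. It also took up to 4 called members of each described list with the largest changes, and nac, glnG and glnA throughout. Near-identical copies were left out. Values of amtB, rutA, fliC, codA and codB that this rule did not pick were added after they were seen. For a gene with 0 reads in a group, the fold is a lower bound from a floor of 3 reads per library, taken at the highest floor. With 1 to 3 reads the ratio of levels is given with its 95% counting interval, and other genes with so few reads are not given as folds.

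TMM scaling, applied to the TPM values, moved the median of all tested genes by over 0.1 log2 in 15 comparisons. Median shifts were 0.69, 0.70, 0.54 and 0.46 in the ΔntrC comparisons on cytosine, against ammonia, against the WT response, against Δnac and against WT. On ammonia, glutamine and cytidine they were -0.24, -0.14 and -0.20 for ΔntrC against Δnac, and -0.21, -0.18 and -0.26 for ΔntrC against WT. They were -0.10 for WT on glutamine, -0.16 and -0.13 for Δnac on glutamine and cytidine, and -0.11 and -0.11 for its difference from WT on cytidine and cytosine. Splits into higher and lower calls that moved by over 10 percentage points, or in which the larger side changed, are given with both scalings.

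The procedure was tested on simulated data for WT on glutamine against ammonia, with 3999 genes, 200 of them changed, in 20 draws. It recovered 92.0% of 2-fold, 99.6% of 4-fold and 100% of 8-fold changes. Changed genes were drawn only from those with at least 20 expected reads, so recovery of rarer genes was not measured. All genes and groups shared a dispersion of 0.0039, so the differing spread of the real pairs was not simulated. Of the genes called, 59.3% were unchanged ones on the TPM scale, because the simulated changes shifted the TPM total, with 12 to 2497 such genes per draw. This exceeded the limit of 10% set for the test. With TMM scaling 7.91% were unchanged, and the limit was then applied to that scaling, after the first outcome had been seen. This test was written after the first run on the real data. In such data, counts of calls on the TPM scale include genes that moved only with the total.

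Alternatives were TMM scaling, quantile normalization, leaving out the 10 most abundant genes, no filter, pseudocounts of 0.1 and 10, no trend or robust options, only the libraries of the genotypes compared, a replicate block, an estimated correlation and leaving out each library in turn. Added after seeing the data were limma voom on the recovered reads, only genes of at least 300 nt, and a fit without the 4 deletion-strain cytosine libraries. Splits of the samples were not counted, since groups held 2 libraries.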

Results

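Transcript levels were measured by RNA-Seq in Escherichia coli K-12 MG1655 grown to mid-log phase on 4 nitrogen sources. These were ammonia in M9 minimal medium, and glutamine, cytidine or cytosine at 2 g/L in W2 minimal medium, each with 0.2% glucose at 37 °C. The wild type (WT) was compared with strains lacking nac (Δnac) or ntrC (ΔntrC). The nac gene encodes the nitrogen assimilation control protein. The ntrC gene, listed as glnG, encodes the response regulator of nitrogen limitation. Each of the 12 groups held 2 libraries, 24 in all. The reads recovered from the deposited TPM values came to 2.27 to 6.31 M per library, with 3962 to 4204 of 4342 genes above 0. Replicate libraries correlated across genes at r = 0.982 to 0.995 on the log2 scale. None of the 12 pairs agreed within sampling noise, with a chi-square per degree of freedom of 1.49 to 27.1. The Δnac pair in cytosine differed most, and the WT pair in ammonia came next at 6.91. Replicates were described as biological duplicates for the 8 WT libraries. For the deletion strains p-values therefore measure only the spread between these samples, which may be technical. The spread of each gene was estimated over all 12 groups together, so this limit also holds for p-values and SE within WT. Replicates differed by a median of 0.256 log2 for Δnac on cytosine and 0.221 for WT on ammonia, against at most 0.162 in the other pairs. SE and p-values of comparisons that use these groups may thus be too small, and their counts of calls too high. The WT ammonia pair enters each WT comparison with ammonia and each difference from the WT response. Changes are given as log2 values on the log2(TPM + 1) scale ± SE, with n = 2 libraries per group. A gene is said to differ where its limma adjusted p was under 0.05 among the 4057 genes tested, and members of gene lists are counted in the same way. Where the count adjusted over the list alone was not the same, it follows in square brackets.

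The deleted genes were examined in each library. In Δnac, nac (b1988) had 3 reads over 8 libraries. In WT it stood at 24.6, 4997, 3526 and 4345 TPM on ammonia, glutamine, cytidine and cytosine. By the highest floor of 3 reads per library, nac was at least 19.4-fold lower than WT on ammonia and at least 8328-fold lower on cytosine. In ΔntrC, glnG (b3868) had 0 reads in 8 libraries. By the same floor it was at least 329-fold, 1912-fold, 959-fold and 574-fold lower than WT on ammonia, glutamine, cytidine and cytosine. The nac transcript stood at 4.23, 6.37, 5.47 and 4.12 TPM in ΔntrC on these sources. The glnA gene (b3870), which encodes glutamine synthetase, stood at 27.5, 21.4, 29.3 and 41.1 TPM in ΔntrC, against 2731, 12089, 10834 and 4765 TPM in WT.

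**Figure D1:**
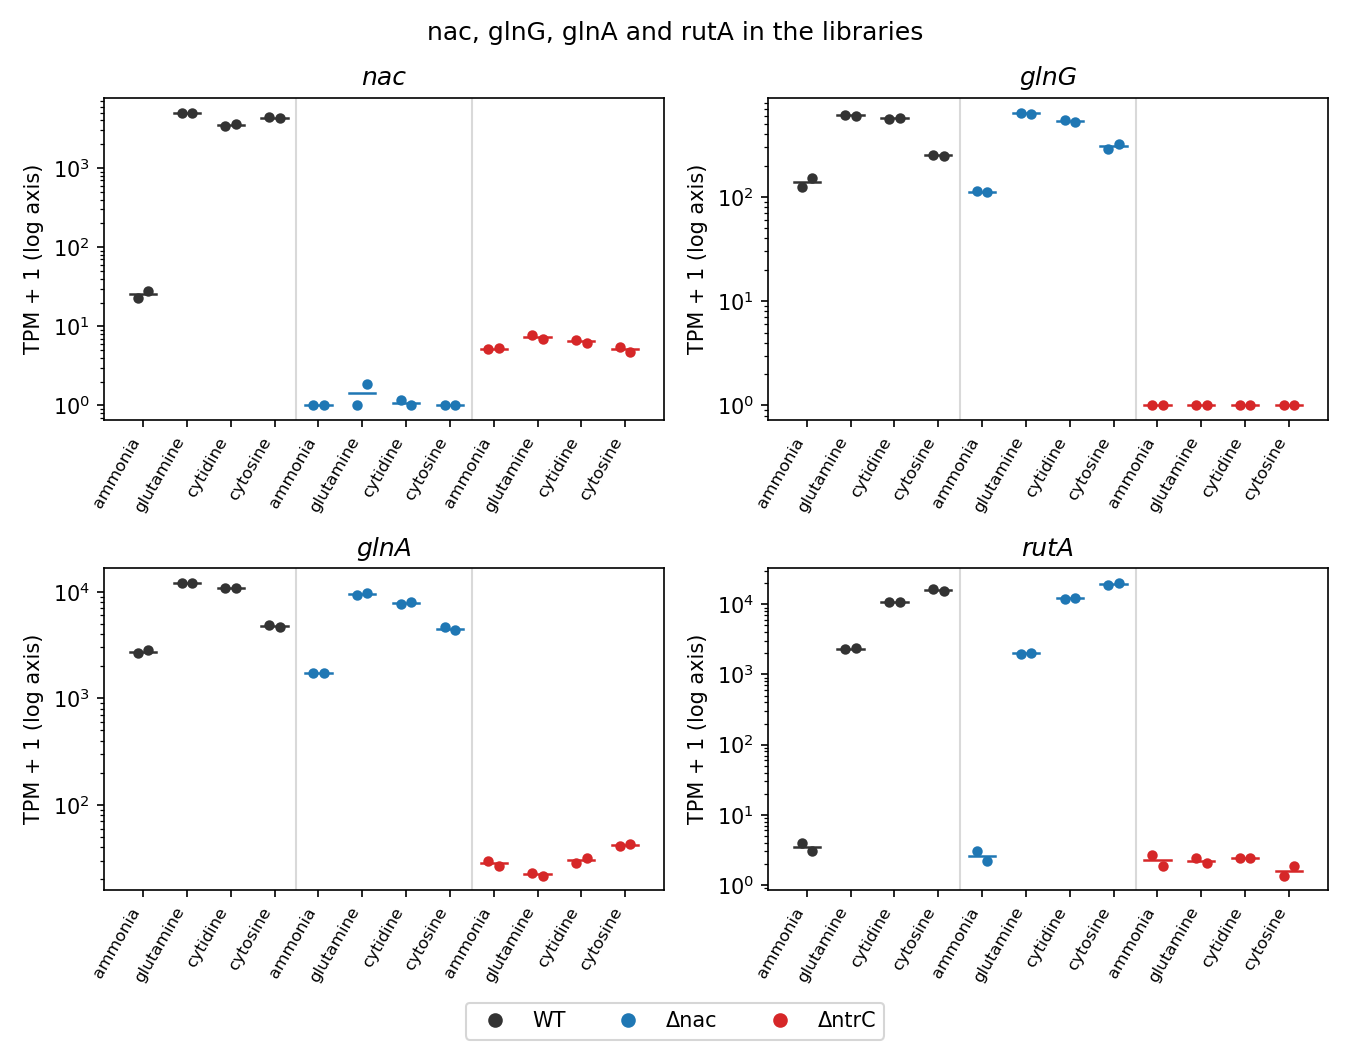
TPM + 1 on a log axis for nac, glnG, glnA and rutA in the 24 libraries, by strain and nitrogen source; each point is 1 library and each line is the mean of 2. In WT, nac stood at 24.6 TPM in ammonia and 4997 in glutamine, and rutA at 2.48 and 2339, while rutA stood at 1.22 in ΔntrC in glutamine.

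The response of WT to each nitrogen source was measured against ammonia. On glutamine, nitrogen scavenging genes were higher, and pyrimidine and arginine synthesis genes lower. The rut operon, which encodes degradation of the pyrimidine ring, held the highest values, with rutA at log2 9.40 ± 0.17, rutB at 8.70 ± 0.35, rutE at 8.33 ± 0.41 and rutD at 8.27 ± 0.34. The rutF transcript had 2 reads in ammonia and a ratio of 771 (95% counting interval 213 to 6375). The lowest were cusC, cusF and cusB of copper and silver efflux, at -5.96 ± 0.19, -5.56 ± 0.30 and -5.51 ± 0.25, and pyrB and pyrI, the subunits of aspartate transcarbamoylase, at -5.91 ± 0.16 and -5.86 ± 0.17. All 35 of 35 NtrC targets rose (adjusted p = 1.97e-26). They included amtB, an ammonium transporter gene, at 7.96 ± 0.14, nac at 7.62 ± 0.21, ddpA of dipeptide transport at 7.57 ± 0.11, glnA at 2.15 ± 0.07 and glnG at 2.14 ± 0.10. All 7 Rut genes rose (adjusted p = 4.74e-08). The 5 genes of the arginine succinyltransferase (Ast) pathway rose too (adjusted p = 4.97e-07), with astB at 5.27 ± 0.13 and astC at 5.18 ± 0.14. Of 16 Nac-activated genes 14 rose and 2 fell (adjusted p = 1.57e-09), with ydcS at 5.79 ± 0.13 and patD at 5.09 ± 0.12. The 2 that fell, named after their values were seen, were codA, for cytosine deaminase, at -0.36 ± 0.11 and codB, for the cytosine transporter, at -0.48 ± 0.17. The codA call ended without WT ammonia library 2 (adjusted p = 0.143) or glutamine library 2 (adjusted p = 0.0517), and the codB call without WT ammonia library 1 or 2 or glutamine library 2 (adjusted p = 0.0535, 0.110 and 0.138). Among ammonia assimilation and Nac-repressed genes 5 of 8 fell and 1 rose (adjusted p = 6.75e-04, and adjusted p = 0.180 with an estimated correlation). The first step of serine synthesis, serA, was at -4.06 ± 0.09, gltB and gltD of glutamate synthase at -2.87 ± 0.08 and -2.81 ± 0.07, and asnB, an asparagine synthetase gene, at 2.59 ± 0.08.

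Other lists on glutamine were as follows. All 10 pyrimidine synthesis genes fell (adjusted p = 2.69e-09), with carA at -3.84 ± 0.10. All 10 arginine synthesis genes fell (adjusted p = 1.86e-13), with argI at -4.81 ± 0.10 and argF at -4.31 ± 0.11. Ribosomal protein genes fell in 53 of 54 cases (adjusted p = 1.70e-22), with rpmE at -1.55. Purine synthesis genes fell in 14 of 16 cases (adjusted p = 5.56e-08, and adjusted p = 0.0720 with an estimated correlation), with purH at -1.14. Iron uptake genes repressed by Fur fell in 24 of 33 cases (adjusted p = 2.71e-11), with fiu at -3.81 and cirA at -3.16. Ribose uptake genes fell in 5 of 6 cases (adjusted p = 0.00321, and adjusted p = 0.111 with an estimated correlation), with rbsD at -1.86. Of 32 other amino acid synthesis genes, 16 fell and 1 rose (adjusted p = 3.19e-05, and adjusted p = 0.321 with an estimated correlation), with metE at -2.75 and ilvB at -2.42. Genes of magnesium limitation, under PhoP, rose in 9 of 9 cases (adjusted p = 6.84e-08), with rstA at 3.18 and mgrB at 3.11. Glutamate-dependent acid resistance genes rose in 11 of 11 cases (adjusted p = 2.47e-05, and adjusted p = 0.298 with an estimated correlation), with gadE at 2.50 and gadC at 2.06. General stress genes under RpoS rose in 16 of 18 cases (adjusted p = 5.29e-09, and adjusted p = 0.0720 with an estimated correlation), with gabD at 3.26 and katE at 1.83. Salvage and nucleoside uptake genes went both ways, with 6 higher and 8 lower of 22 (adjusted p = 0.423). Among them uraA, the uracil permease gene, was at -3.78 ± 0.16 and upp at -2.26 ± 0.07, and the list's median of 0.12 and mean of -0.25 differed in sign. The heat shock list had 7 of 16 higher (adjusted p = 0.107; rpoH 0.77). The flagella and chemotaxis list had 5 higher and 14 lower of 51 [4 higher, 13 lower] (adjusted p = 0.0773; flgD -2.47). The phosphate (PhoB) list had 8 higher and 1 lower of 15 [9 higher, 1 lower] (adjusted p = 0.132; phoH 1.15), and the sulfur list 1 higher and 8 lower of 22 (adjusted p = 0.0675; cysJ -0.80). Over all genes, 1997 of 4057 differed, 1148 higher and 849 lower, and with TMM scaling 965 were higher and 1031 lower. Medium changed together with source in each comparison with ammonia, so these 2 factors cannot be told apart.

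On cytidine, the rut operon again held the highest values in WT, and pyrimidine synthesis and copper efflux genes the lowest. The rutA transcript stood at log2 11.62 ± 0.17, rutB at 10.90 ± 0.35, rutE at 10.37 ± 0.41 and rutD at 10.29 ± 0.34, and the rutF ratio was 2648 (95% counting interval 733 to 21866). The lowest were pyrB at -7.50 ± 0.16, pyrI at -7.03 ± 0.17, cusC at -6.42 ± 0.19, cusF at -6.30 ± 0.30 and cusB at -5.48 ± 0.25. NtrC targets rose in 35 of 35 cases (adjusted p = 2.27e-35), with amtB at 7.23, nac at 7.11, glnA at 1.99 and glnG at 2.04. Rut genes rose in 7 of 7 cases (adjusted p = 1.17e-12) and Ast genes in 5 of 5 (adjusted p = 2.01e-09; astA 4.74). Nac-activated genes rose in 14 of 16 cases (adjusted p = 8.17e-12), with ydcS at 4.54 and gabT at 4.05. The 2 that fell, named after their values were seen, were codA at -1.09 ± 0.11 and codB at -1.26 ± 0.17. Among assimilation and Nac-repressed genes 6 fell and 1 rose of 8 (adjusted p = 1.03e-04, and adjusted p = 0.134 with an estimated correlation), with serA at -2.91 ± 0.09 and asnA, an asparagine synthetase gene, at -1.76 ± 0.12. In the acid resistance list 9 fell and 1 rose of 11 (adjusted p = 6.42e-05, and adjusted p = 0.321 with an estimated correlation), with gadE, its regulator, at -1.92 ± 0.65 and hdeD at -1.88 ± 0.32. The gadE call ended with voom on the recovered reads (adjusted p = 0.250; 1.30e-07 to 0.250 over the alternatives) and without any 1 of the 4 libraries (adjusted p = 0.0696 to 0.121). Iron uptake genes rose in 25 and fell in 1 of 33 cases (adjusted p = 9.88e-07, and adjusted p = 0.101 with an estimated correlation), with fhuE at 1.58 ± 0.14 and fes at 1.56 ± 0.12. The salvage list had 6 higher and 7 lower of 22 [7 higher, 7 lower] (adjusted p = 0.496; median 0.05, mean -0.22). Within it cdd, for cytidine deaminase, was at 2.64 ± 0.14 and udp, for uridine phosphorylase, at 1.76 ± 0.10. In total 1418 genes differed, 734 higher and 684 lower.

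Other lists on cytidine were mostly lower. Pyrimidine synthesis genes fell in 9 of 10 cases (adjusted p = 2.32e-12; carA -3.52). Purine synthesis genes fell in 15 of 16 cases [1 higher, 15 lower] (adjusted p = 3.39e-12; purT -1.76, purD -1.58). Arginine synthesis genes fell in 9 of 10 cases (adjusted p = 1.12e-06, and adjusted p = 0.101 with an estimated correlation; argG -1.14). Ribose uptake genes fell in 5 of 6 cases [0 higher, 6 lower] (adjusted p = 6.67e-05; rbsA -2.01). Ribosomal protein genes fell in 41 of 54 cases [0 higher, 47 lower] (adjusted p = 1.31e-12, and adjusted p = 0.110 with an estimated correlation; rplL -0.77). The other amino acid list had 3 higher and 18 lower of 32 [5 higher, 18 lower] (adjusted p = 2.88e-05, and adjusted p = 0.321 with an estimated correlation; metF -1.55). The flagella list had 2 higher and 15 lower of 51 [2 higher, 14 lower] (adjusted p = 0.00770, and adjusted p = 0.182 with an estimated correlation; fliA -2.40). The sulfur list had 9 lower of 22 [0 higher, 10 lower] (adjusted p = 0.00441, and adjusted p = 0.313 with an estimated correlation; cysJ -0.93). Higher were the PhoP list in 9 of 9 cases (adjusted p = 1.68e-11; mgtA 3.51, rstA 3.43) and the RpoS list in 16 of 18 (adjusted p = 8.37e-09, and adjusted p = 0.0755 with an estimated correlation; gabD 3.60, poxB 2.03). The heat shock list had 2 higher and 2 lower of 16 [1 higher, 2 lower] (adjusted p = 0.810; rpoH 0.48), and the PhoB list 2 of 15 higher [0 higher, 0 lower] (adjusted p = 0.456; ugpC 0.38). The ugpC call ended without WT ammonia library 1 (adjusted p = 0.0578) or cytidine library 1 (adjusted p = 0.216).

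On cytosine, the rut operon held the highest values in WT, and genes of pyrimidine synthesis and uracil uptake were among the lowest. The rutA transcript stood at log2 12.16 ± 0.17, rutB at 11.36 ± 0.35, rutD at 10.75 ± 0.34 and rutE at 10.63 ± 0.41, and the rutF ratio was 3528 (95% counting interval 976 to 29134). The lowest were pyrB at -7.27 ± 0.16, pyrI at -7.05 ± 0.17, uraA at -4.58 ± 0.16, ridA, an imine deaminase gene, at -4.02 ± 0.16 and carA, for carbamoyl phosphate synthetase, at -3.66 ± 0.10. NtrC targets rose in 33 of 35 cases (adjusted p = 2.95e-20), with nac at 7.42, amtB at 6.38, glnA at 0.80 and glnG at 0.86. Rut genes rose in 7 of 7 cases (adjusted p = 1.09e-10) and Ast genes in 5 of 5 (adjusted p = 3.08e-07; astB 4.00). Nac-activated genes rose in 14 of 16 cases (adjusted p = 1.27e-10), with ydcS at 4.44 and patD at 4.06. The remaining 2, named after their values were seen, were codA at -0.21 ± 0.11 (adjusted p = 0.118) and codB at -0.04 ± 0.17 (adjusted p = 0.868). Among assimilation and Nac-repressed genes 5 fell and 2 rose of 8 (adjusted p = 0.0163, and adjusted p = 0.342 with an estimated correlation; serA -2.72, gltF -1.97). In total 1991 genes differed, 952 higher and 1039 lower.

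Nucleotide synthesis lists were lower on cytosine. All 10 pyrimidine synthesis genes fell (adjusted p = 1.72e-09; carB -3.41), as did all 16 purine synthesis genes (adjusted p = 2.27e-10; purD -1.77, purN -1.67). Arginine synthesis genes fell in 9 of 10 cases [0 higher, 10 lower] (adjusted p = 0.00179, and adjusted p = 0.280 with an estimated correlation; argG -1.22). Ribosomal protein genes fell in 52 of 54 cases (adjusted p = 1.97e-17, and adjusted p = 0.0582 with an estimated correlation; rpmG -1.43, rplM -1.34). In the other amino acid list 7 rose and 19 fell of 32 [7 higher, 20 lower] (adjusted p = 0.160), and the leucine synthesis genes leuA, leuB, leuC and leuD rose by 1.81, 1.42, 1.33 and 1.27. Acid resistance genes rose in 9 of 11 cases (adjusted p = 1.84e-04, and adjusted p = 0.351 with an estimated correlation; gadE 2.49). RpoS-dependent genes rose in 13 of 18 cases (adjusted p = 1.38e-07, and adjusted p = 0.103 with an estimated correlation; gabD 2.85, poxB 2.53). PhoP-dependent genes rose in 9 of 9 cases (adjusted p = 1.10e-08; mgtA 3.91, rstA 2.82). The iron list had 9 higher and 7 lower of 33 [9 higher, 8 lower] (adjusted p = 0.958; fiu -2.39, sufA 0.98). Its mean of -0.05 and median of -0.04 lay below 0 while the test pointed up. The salvage list had 6 higher and 8 lower of 22 (adjusted p = 0.342; upp -3.32, median 0.07, mean -0.48). In the ribose list 3 of 6 were lower (adjusted p = 0.125; rbsK -0.99), and in the heat shock list 7 of 16 were higher (adjusted p = 0.201; clpB 0.71). The flagella list had 5 higher and 15 lower of 51 [5 higher, 14 lower] (adjusted p = 0.572; flgD -2.06). The PhoB list had 2 higher and 1 lower of 15 (adjusted p = 0.595; phoB 0.48), and the sulfur list 6 higher and 4 lower of 22 [5 higher, 4 lower] (adjusted p = 0.572; ssuA 1.05). The phoB call ended without WT ammonia library 1 (adjusted p = 0.139) or either cytosine library (adjusted p = 0.0632 and 0.0796). The ssuA call (adjusted p = 0.0499) ended without any 1 of the 4 libraries (adjusted p = 0.0931 to 0.193).

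Across the 3 WT comparisons with ammonia, 491 genes, rutA and amtB among them, were higher in each, and 507, pyrB and carA among them, were lower in each. Independent lists of these sizes would share 48.7 and 36.7 genes. In 100 draws of unchanged libraries simulated against the same ammonia controls, limma called at most 1 gene per comparison and 0 in all 3, so this says little of lists this long. Lists of the observed sizes, ranked by p in those draws, shared means of 254 genes for higher and 216 for lower (highest 285 and 237), a measure chosen after the data were seen. The draws gave each gene the same spread in all WT libraries. The real WT ammonia libraries differed by a median of 0.221 log2, against 0.112 to 0.128 for the other WT pairs. These means may thus be too low for the real controls. The 2 ammonia libraries could not be split, so part of the overlap may come from the shared controls. The change from M9 to W2 medium was also common to the 3 comparisons, and its part cannot be told apart from that of nitrogen source.

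**Figure D2:**
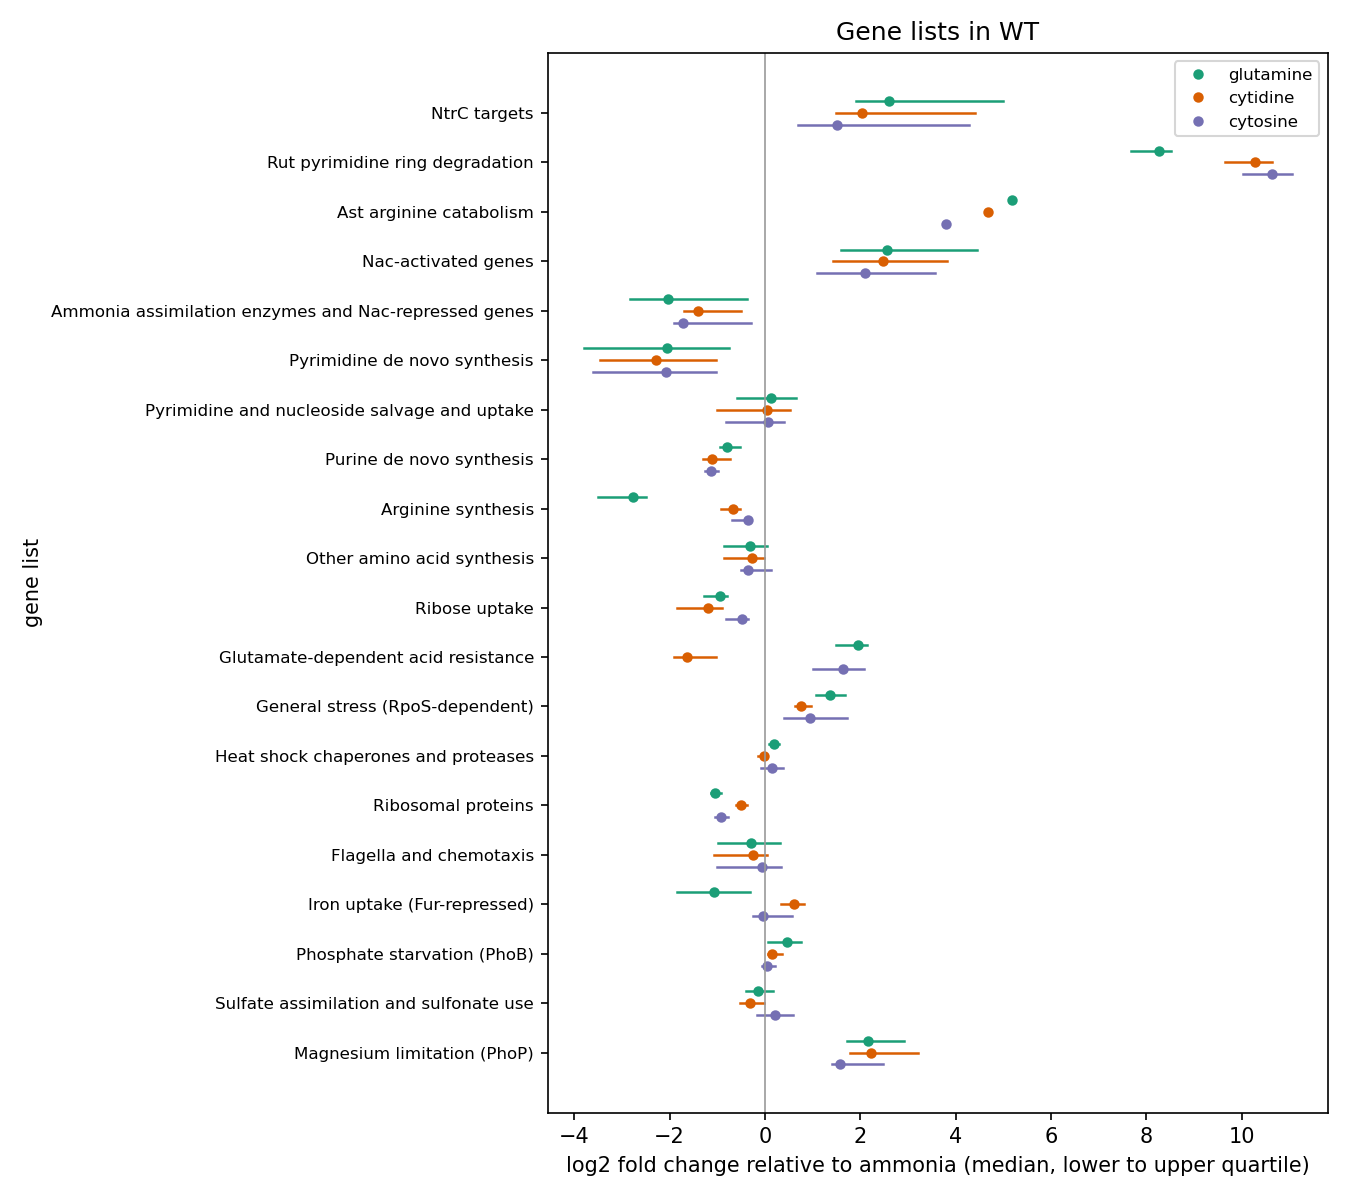
Median log2 fold change of the 20 gene lists in WT on glutamine, cytidine and cytosine relative to ammonia (x axis, log2), with bars from the lower to the upper quartile of each list's genes. The NtrC list has medians of 2.60, 2.04 and 1.51, and the acid resistance list lies at 1.95 in glutamine, -1.63 in cytidine and 1.65 in cytosine.

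Cytosine and cytidine, both in W2 medium, were also compared with each other in WT. Acid resistance genes were higher on cytosine, and iron uptake genes higher on cytidine. The highest values on cytosine were gadE at 4.41 ± 0.65, cusC at 4.35 ± 0.19 and gadC, an antiporter gene, at 3.92 ± 0.15. The lowest were zinT and znuA, for zinc-binding proteins, at -9.49 ± 0.52 and -5.77 ± 0.11, and ykgM, a ribosomal protein paralogue, at -6.75 ± 0.45. Of 11 acid resistance genes 10 were higher and 1 lower (adjusted p = 4.25e-13, and adjusted p = 0.0807 with an estimated correlation). Of 33 iron uptake genes 1 was higher and 21 lower [1 higher, 22 lower] (adjusted p = 5.31e-07, and adjusted p = 0.0947 with an estimated correlation; cirA -2.07, entF -1.36). Of 35 NtrC targets 4 were higher and 21 lower [4 higher, 25 lower] (adjusted p = 1.16e-06, and adjusted p = 0.0785 with an estimated correlation), with argT at -1.39, glnA at -1.19 and glnG at -1.18. Ast genes were lower in 5 of 5 cases (adjusted p = 9.87e-04, and adjusted p = 0.103 with an estimated correlation; astE -0.98). Within the Rut list 2 of 7 were higher (adjusted p = 0.0618), with rutA at 0.55 ± 0.17 and rutG at 0.53 ± 0.15. The rutA call ended without any 1 of the 4 libraries (adjusted p = 0.0698 to 0.123), and the rutG call without cytidine library 1 or 2 or cytosine library 2 (adjusted p = 0.0732, 0.0602 and 0.0961). The nac transcript stood at 0.30 ± 0.21 (adjusted p = 0.303; 1.33e-08 to 0.806 over the alternatives, of which 3 called it). In total 1226 genes differed, 417 higher and 809 lower.

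The same sources were compared with ammonia in Δnac. The rut, ast and NtrC target genes rose, and flagellar genes fell. On glutamine, cytidine and cytosine the rutA transcript rose by log2 9.59, 12.20 and 12.87, amtB by 8.29, 8.12 and 7.16, astA by 7.37, 6.61 and 6.32, glnA by 2.45, 2.19 and 1.38 and glnG by 2.50, 2.25 and 1.45. NtrC targets rose in 34, 34 and 32 of 35 cases [35, 34 and 32 higher, 0, 0 and 0 lower] (adjusted p = 6.92e-25, 9.22e-30 and 2.18e-13). The list holds nac, the deleted gene, which was called on none of these sources and accounts for the bracketed 35 on glutamine. Its value there of 0.45 ± 0.21 rests on 2 reads, against 0 on ammonia. Rut genes rose in 7, 7 and 7 of 7 (adjusted p = 8.76e-08, 4.67e-11 and 1.02e-07) and Ast genes in 5, 5 and 5 of 5 (adjusted p = 1.40e-07, 4.46e-09 and 3.79e-06). Flagellar genes fell in 51, 51 and 51 of 51 cases (adjusted p = 1.39e-29, 1.07e-43 and 2.17e-20), with flgD, a hook assembly gene, at -6.93, -6.85 and -6.92. The mean log2(TPM + 1) of these genes was 6.51 and 6.50 in the Δnac ammonia libraries, against 1.87 to 2.87 in the other 22. Pyrimidine synthesis genes fell in 9, 9 and 8 of 10 cases (adjusted p = 1.40e-07, 8.36e-12 and 4.06e-06), with pyrB at -5.56, -7.17 and -7.00. The Nac-activated list had 8, 7 and 8 higher and 8, 8 and 8 lower of 16 [8, 8 and 8 higher, 8, 8 and 8 lower] (adjusted p = 0.277, 0.257 and 0.267), with codB at -2.46, -3.08 and -3.51. The genes called numbered 1973, 1647 and 2560. They were 1235 higher and 738 lower on glutamine (with TMM scaling 897 and 1024), 1064 and 583 on cytidine (with TMM scaling 791 and 787), and 1402 and 1158 on cytosine (with TMM scaling 1261 and 1284). The pooled spread may understate that of the Δnac cytosine pair, so the 2560 calls on cytosine may be too many.

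Whether the Δnac response differed from that of WT was tested as an interaction, in which a constant offset between the strains' libraries cancels. An offset that differs between sources would not cancel, here or for ΔntrC, and cannot be told apart from strain. Relative to the ammonia level of its own strain, Nac-activated genes were lower in Δnac than in WT, and asnA, serA and the ast genes were higher. Nac-activated genes were lower in 16, 16 and 16 of 16 cases on glutamine, cytidine and cytosine (adjusted p = 1.63e-34, 2.38e-37 and 6.36e-26). Among them ydcS, for a transporter's binding protein, was at -4.89, -3.74 and -3.76 and ydcT at -4.26, -3.22 and -3.28. Within Δnac ydcS rose by 0.89, 0.80 and 0.68, against 5.79, 4.54 and 4.44 in WT, whereas codB was at -2.46, -3.08 and -3.51, against -0.48, -1.26 and -0.04 in WT. The asnA difference was 5.49 ± 0.17, 5.50 ± 0.17 and 5.24 ± 0.17, and that of serA 4.12, 2.93 and 2.33. Against ammonia asnA was at 3.49, 3.75 and 3.66 within Δnac and -1.99, -1.76 and -1.57 in WT. The serA values were 0.06, 0.02 and -0.39 within Δnac (adjusted p = 0.586, 0.922 and 0.00108) and -4.06, -2.91 and -2.72 in WT. With quantile normalization the value within Δnac on glutamine was 0.27 and was called (adjusted p = 0.0146). Assimilation and Nac-repressed genes were higher in 5, 5 and 4 of 8 cases [6, 6 and 4 higher, 0, 0 and 0 lower] (adjusted p = 1.49e-09, 5.18e-11 and 2.42e-05, and adjusted p = 0.0265, 0.0185 and 0.107 with an estimated correlation). Ast genes were higher in 5, 5 and 5 of 5 cases (adjusted p = 5.97e-06, 2.95e-05 and 2.71e-06), with astA at 2.19, 1.87 and 2.53. Against WT on the same source, 5 Ast genes were lower in Δnac on ammonia, 1 of 5 was higher on glutamine, 1 was lower on cytidine and 5 were higher on cytosine (adjusted p = 0.545, 0.586 and 0.0277, and adjusted p = 0.753, 0.779 and 0.262 with an estimated correlation for the last 3 sources). Flagellar genes were lower in 49, 49 and 50 of 51 cases [0, 0 and 0 higher, 50, 49 and 50 lower] (adjusted p = 2.23e-47, 1.89e-62 and 6.66e-39), with fliC, the flagellin gene, at -3.45, -5.71 and -5.73. The Δnac ammonia libraries, whose flagellar levels stood apart, enter all 3 of these counts. On glutamine, cytidine and cytosine the list median of Δnac against WT was 0.51, 0.24 and 0.27. Iron uptake genes were higher in 30 of 33 cases on glutamine [30 higher, 1 lower] (adjusted p = 9.41e-29; entF 3.12). On cytidine they were lower in 14 of 33 [0 higher, 16 lower] (adjusted p = 7.60e-15; cirA -1.62). On cytosine 7 were higher and 1 lower [6 higher, 1 lower] (adjusted p = 0.241). Within Δnac the iron list had 19, 5 and 12 higher and 3, 5 and 7 lower [21, 5 and 12 higher, 3, 5 and 7 lower] (adjusted p = 0.0199, 0.351 and 0.438, and adjusted p = 0.408, 0.744 and 0.784 with an estimated correlation), and with TMM scaling 3 higher and 8 lower on cytidine, where its test and mean of -0.02 pointed down and its median was 0.08. The call on glutamine ended with TMM scaling (adjusted p = 0.0692; 0.0134 to 0.408 over the alternatives). For the Rut list limma called 0, 0 and 1 of 7 genes [0, 0 and 0 higher, 0, 0 and 0 lower], against 1, 1 and 2 at an unadjusted p under 0.05 (adjusted p = 0.779, 0.773 and 0.509 for the list). The rutA difference was 0.19, 0.58 and 0.71 (adjusted p = 0.685, 0.141 and 0.0408), and with TMM scaling the call on cytosine ended (adjusted p = 0.116; 0.00338 to 0.323 over the alternatives). It also ended without WT ammonia library 1, either WT cytosine library, Δnac ammonia library 2 or Δnac cytosine library 2 (adjusted p = 0.0720 to 0.190). That of glnA was 0.31, 0.20 and 0.57 (adjusted p = 0.0401, 0.222 and 2.93e-04) and that of glnG 0.36, 0.20 and 0.58 (adjusted p = 0.0863, 0.389 and 0.00373). The glnA call on glutamine ended with TMM scaling (adjusted p = 0.189; 3.29e-04 to 0.189 over the alternatives) and without any 1 of the 8 libraries except WT ammonia library 1 (adjusted p = 0.0579 to 0.137). Calls numbered 678 on glutamine (407 higher, 271 lower), 567 on cytidine (351 and 216) and 1086 on cytosine (590 and 496). With TMM scaling the splits were 325 and 333, 239 and 267, and 398 and 644. The pooled spread may understate that of the WT ammonia pair, which enters all 3 counts, and of the Δnac cytosine pair, which enters the last. These counts may thus be too high.

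In ΔntrC the rut, ast and NtrC target lists passed no list test against ammonia, and pyrimidine synthesis genes fell. The rutA transcript stood at 1.27, 1.22, 1.45 and 0.598 TPM on ammonia, glutamine, cytidine and cytosine. Its log2 values against ammonia were -0.01, 0.14 and -0.50 (adjusted p = 0.986, 0.615 and 0.0188). With TMM scaling the value on cytosine was -0.16 (adjusted p = 0.531; 0.0117 to 0.913 over the alternatives), and the call also ended without ΔntrC library 1 of ammonia or of cytosine (adjusted p = 0.312 and 0.249). Pyrimidine synthesis genes fell in 9, 9 and 10 of 10 cases (adjusted p = 8.89e-08, 2.03e-17 and 7.01e-06), with pyrB at -2.52, -6.24 and -6.30 and pyrI at -2.41, -6.39 and -6.67. With TMM scaling 9 of them fell on cytosine. The NtrC list had 12, 13 and 5 higher and 4, 2 and 17 lower of 35 [12, 15 and 5 higher, 5, 2 and 17 lower] (adjusted p = 0.481, 0.101 and 0.512), with ddpF at 1.18 ± 0.24 on glutamine. The Ast list had 2, 0 and 0 higher and 0, 2 and 1 lower of 5 [5, 0 and 0 higher, 0, 2 and 0 lower] (adjusted p = 0.0711, 0.179 and 0.274), with astA at -0.66 ± 0.11 on cytidine. On cytosine the medians of both lists, -0.37 and -0.18, lay below 0 while their tests pointed up, and TMM scaling gave 11 higher and 10 lower NtrC targets and 5 higher Ast genes. The Ast list was then called up (adjusted p = 0.0485; 0.0435 to 0.573 over the alternatives). The glnA transcript stood at -0.34, 0.09 and 0.57 (adjusted p = 7.81e-04, 0.364 and 9.89e-07). The highest on glutamine were ynfM, a transporter gene, at 4.33 ± 0.11, gadC at 3.57 ± 0.15 and mdtF, an efflux pump gene, at 3.18 ± 0.13. The lowest were ompF, a porin gene, at -4.31 ± 0.07, cusF at -3.96 ± 0.30 and cusC at -3.90 ± 0.19. On cytidine ynfM, yjcB and tsgA were highest at 3.34 ± 0.11, 3.22 ± 0.30 and 2.32 ± 0.18, and uraA was at -4.85 ± 0.16. On cytosine ynfM was at 4.27 ± 0.11, ffs, the signal recognition particle RNA, at 5.20 ± 0.39, and uraA at -6.03 ± 0.16. The ffs rise in ΔntrC was from 54 reads on ammonia to 1870 on cytosine, against 27946 and 55239 in WT. Its level thus stayed far below that of WT on both sources. In Δnac ffs had few reads too, 202 on ammonia and 827 on cytosine. Strain and a possible batch cannot be told apart in this comparison with WT. Acid resistance genes rose in 11 of 11 cases on glutamine (adjusted p = 1.67e-10, and adjusted p = 0.119 with an estimated correlation) and fell in 10 on cytidine (adjusted p = 3.37e-11, and adjusted p = 0.107 with an estimated correlation; gadE -3.66). On cytosine 7 rose, and with TMM scaling 11 (adjusted p = 4.30e-08, and adjusted p = 0.173 with an estimated correlation). The gadE call on cytidine ended with voom (adjusted p = 0.0872; 3.85e-09 to 0.0872 over the alternatives). Calls numbered 1408 on glutamine (780 higher, 628 lower, with TMM scaling 635 and 751), 1194 on cytidine (779 and 415, with TMM scaling 571 and 547) and 2565 on cytosine (262 and 2303, with TMM scaling 1015 and 1062). In the cytosine libraries of ΔntrC the 6S RNA ssrS held 37.7 to 38.3% of TPM, against 2.64 to 18.9% in the other 22.

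Against the WT response, NtrC targets were lower in ΔntrC on each source by the interaction test. They were lower in 35, 34 and 34 of 35 cases on glutamine, cytidine and cytosine [0, 0 and 0 higher, 35, 35 and 35 lower] (adjusted p = 9.57e-51, 7.01e-46 and 3.62e-15), with amtB at -7.36, -6.78 and -6.54 and ddpA at -7.15, -6.44 and -5.78. These counts and tests include glnG, the deleted gene, whose differences of -2.14, -2.04 and -0.86 only mirror its WT response. Rut genes were lower in 7, 7 and 7 of 7 cases (adjusted p = 1.32e-14, 1.63e-17 and 2.64e-08), with rutA at -9.41, -11.48 and -12.66. Ast genes were lower in 5, 5 and 5 of 5 (adjusted p = 2.32e-12, 3.75e-13 and 2.53e-05), with astA at -4.94, -5.40 and -4.06. Nac-activated genes were lower in 16, 15 and 16 of 16 (adjusted p = 1.55e-23, 1.01e-21 and 3.37e-11), with ydcS at -5.56, -4.43 and -4.49. The PhoP list rose within ΔntrC too, with 8, 8 and 4 of 9 genes higher against ammonia and 2 lower on cytosine (adjusted p = 2.25e-06, 6.58e-09 and 7.91e-05), and with TMM scaling 9 were higher on cytosine. Its response was lower than in WT in 7, 8 and 8 of 9 cases (adjusted p = 3.17e-08, 2.35e-09 and 7.64e-04), with mgtA at -1.70, -1.42 and -2.11. Higher in ΔntrC were serA on glutamine at 3.91 ± 0.13, and cusC, cusF and cusB on cytidine at 5.59 ± 0.28, 5.52 ± 0.43 and 4.62 ± 0.36. The zinT difference on cytidine was -10.81 ± 0.73. The glnA difference was -2.49, -1.90 and -0.24 (adjusted p = 1.26e-12, 7.74e-11 and 0.0511), and on cytosine it turned to 0.50 with TMM scaling. Calls numbered 861 on glutamine (385 higher, 476 lower), 944 on cytidine (552 and 392, with TMM scaling 430 and 468) and 2306 on cytosine (122 and 2184). With TMM scaling 1134 genes were called on cytosine, 541 higher and 593 lower. Of the lists above, 32 NtrC targets, 7 Rut, 5 Ast, 16 Nac-activated and 6 PhoP-dependent genes were then lower.

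The deletion strains, whose RNA was described with the same quantification, were compared with each other on each source. NtrC targets were lower in ΔntrC than in Δnac on glutamine, cytidine and cytosine, and flagellar genes were lower on ammonia. NtrC targets were lower in 32, 32 and 32 of 35 cases on those 3 sources (adjusted p = 3.18e-20, 3.70e-20 and 2.27e-10), and with TMM scaling in 32 on cytosine. The list holds both deleted genes, so on each source glnG counts as lower and nac as higher through the deletions themselves. The amtB transcript was at -8.42, -8.39 and -8.04, glnA at -8.72, -8.02 and -6.73 and rutA at -9.81, -12.28 and -13.58. On ammonia 13 NtrC targets were higher and 17 lower (adjusted p = 0.0591), with glnA at -5.92 ± 0.07. On glutamine glnK and ddpX had 3 reads each in ΔntrC. They were 2408-fold (95% counting interval 823 to 11683) and 3753-fold (1283 to 18205) higher in Δnac. On ammonia 50 of 51 flagellar genes were lower (adjusted p = 4.83e-21), with flgE, the hook protein gene, at -6.22 ± 0.23 and fliA, the flagellar sigma factor gene, at -6.11 ± 0.36. On glutamine, cytidine and cytosine 4, 10 and 0 were higher and 18, 8 and 24 lower [3, 8 and 0 higher, 17, 7 and 20 lower] (adjusted p = 0.0664, 0.784 and 0.849), and with TMM scaling 7 higher and 12 lower on cytidine. The list medians on cytidine and cytosine, 0.03 and -0.74, had the opposite sign to their tests. Among the highest in ΔntrC was rmf, for a ribosome modulation factor, at 6.38 ± 0.18, 6.67 ± 0.18 and 6.62 ± 0.18 on ammonia, glutamine and cytidine. The small RNA glmY was at 6.64 ± 0.20, 7.75 ± 0.20, 8.65 ± 0.20 and 7.29 ± 0.20 on ammonia, glutamine, cytidine and cytosine, and ryfD at 7.47 ± 0.16 on cytosine. With 0 reads in Δnac, acrZ was at least 23.1-fold higher on ammonia and rpmH at least 8.19-fold higher on glutamine, by the floor of 3 reads per library. These 5 genes are annotated at under 300 nt. Genes from 150 to under 300 nt had median log2 values of 1.69, 1.56, 1.71 and 0.98 on ammonia, glutamine, cytidine and cytosine, against 0.24, 0.14, 0.15 and -0.63 for longer genes. Calls numbered 2808 on ammonia (1758 higher, 1050 lower, with TMM scaling 1376 and 1316) and 2660 on glutamine (1545 and 1115). They numbered 2630 on cytidine (1560 and 1070, with TMM scaling 1209 and 1309) and 2756 on cytosine (549 and 2207, with TMM scaling 1214 and 1302).

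**Figure D3:**
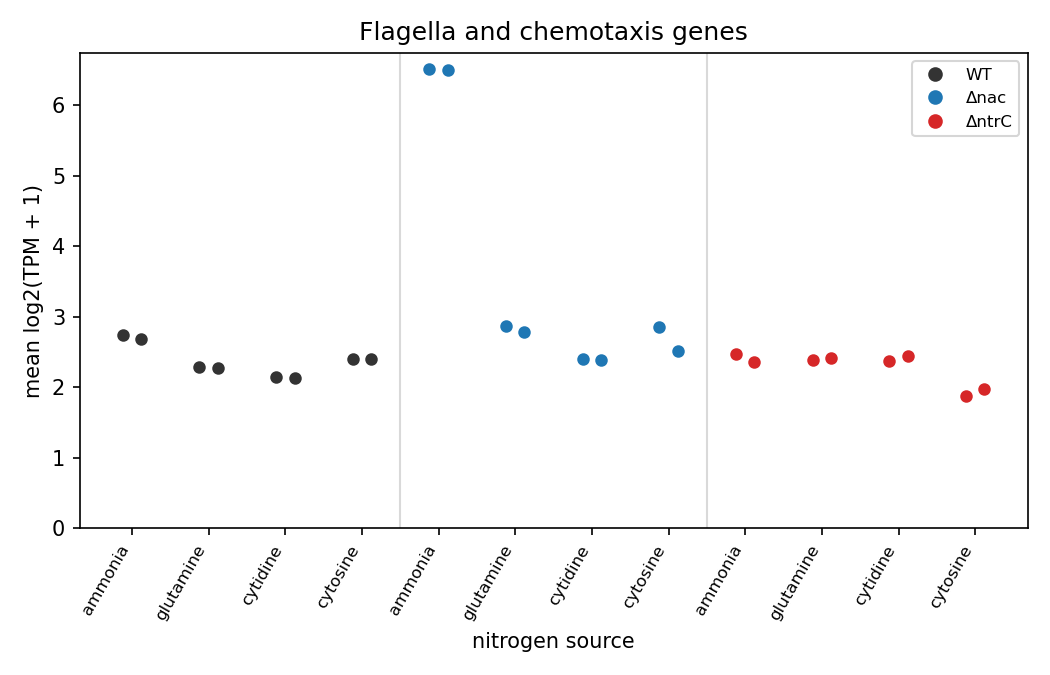
Mean log2(TPM + 1) of the 51 flagella and chemotaxis genes in each of the 24 libraries (y axis), by strain and nitrogen source (x axis); each point is 1 library. The Δnac libraries in ammonia stand at 6.51 and 6.50, above the other 22.

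Each deletion strain was also compared with WT on the same source. In Δnac, flagellar genes were higher on ammonia, and asnA was higher on the other sources. On ammonia tar, a chemoreceptor gene, flu, for antigen 43, and fliC were the highest at 5.72 ± 0.25, 5.58 ± 0.12 and 5.57 ± 0.12. Flagellar genes were higher in 51 of 51 cases (adjusted p = 8.83e-44). Heat shock genes were higher in 14 of 16 cases (adjusted p = 9.78e-10; ibpA 1.48). RpoS-dependent genes were lower in 16 of 18 (adjusted p = 7.97e-09, and adjusted p = 0.0753 with an estimated correlation; bolA -1.46) and Ast genes in 5 of 5 (adjusted p = 5.49e-05; astA -2.25). On glutamine, cytidine and cytosine 1, 13 and 5 heat shock genes were higher and 8, 0 and 0 lower [2, 13 and 4 higher, 9, 0 and 0 lower] (adjusted p = 0.0384, 9.97e-06 and 0.180, and adjusted p = 0.466, 0.126 and 0.637 with an estimated correlation), and with TMM scaling 2 higher and 2 lower on cytosine. Also on these sources 1, 1 and 4 RpoS-dependent genes were higher and 8, 9 and 7 lower [1, 1 and 4 higher, 9, 10 and 7 lower] (adjusted p = 7.43e-04, 9.02e-04 and 0.214, and adjusted p = 0.286, 0.290 and 0.689 with an estimated correlation). The asnA transcript was there at 5.69, 5.71 and 5.44. On glutamine flu was at 5.67 and serA at 4.28, and on cytidine flu was at 5.66 and tabA at 4.46. On cytosine tabA was at 4.46. The glnA transcript stood at -0.66 on ammonia and -0.36, -0.46 and -0.09 on the other 3 sources (adjusted p = 0.330 for cytosine). With quantile normalization it turned to 0.12 on glutamine and 0.39 on cytosine, and its call on cytidine ended (adjusted p = 0.368; 6.36e-15 to 0.368 over the alternatives). Among the lowest was the small RNA ryhB on ammonia, with 1 read in Δnac and 208-fold more in WT (95% counting interval 36.9 to 8228). On cytidine zinT was at -9.21 ± 0.52. Tested genes under 150 nt had a median log2 of -3.93 on ammonia, against 0.00 for genes of 300 nt or more. Calls numbered 1398 on ammonia (648 higher, 750 lower) and 1458 on glutamine (838 and 620, with TMM scaling 710 and 721). They numbered 1511 on cytidine (932 and 579, with TMM scaling 719 and 684) and 1764 on cytosine (926 and 838, with TMM scaling 765 and 981). The WT and deletion-strain libraries were submitted apart. RNA of WT and of the deletion strains was quantified with different instruments, and the design text covers the 8 WT libraries only. Strain and a possible batch cannot be told apart in comparisons with WT.

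In ΔntrC, NtrC targets were lower than in WT on glutamine, cytidine and cytosine, and yjbE, rcsA and fcl were the highest on ammonia. NtrC targets were lower in 33, 33 and 35 of 35 cases on those 3 sources (adjusted p = 5.58e-21, 2.25e-20 and 1.86e-13), and with TMM scaling in 33 on cytosine. The NtrC counts and tests on each source include glnG, the deleted gene. The glnA transcript was at -9.08, -8.48 and -6.82 and rutA at -10.04, -12.11 and -13.29. On ammonia 5 NtrC targets were higher and 22 lower (adjusted p = 1.22e-04, and adjusted p = 0.156 with an estimated correlation), with glnA at -6.59 ± 0.07. There yjbE was at 6.84 ± 0.31, rcsA, a regulator gene of colanic acid synthesis, at 6.06 ± 0.31 and fcl, a GDP-fucose synthesis gene, at 5.35 ± 0.25. With 0 reads in ΔntrC on ammonia, the small RNA chiX, annotated at under 150 nt, was at least 254-fold lower. On glutamine asnA was at 5.55 ± 0.12, yjjV at 5.33 ± 0.19 and rcsA at 5.25 ± 0.31. On cytidine cusC was at 6.06 ± 0.19, yjbE at 5.44 ± 0.31 and rcsA at 5.04 ± 0.31. On cytosine asnA was at 4.69 ± 0.12 and csrC, a small RNA, at 4.37 ± 0.09. Purine synthesis genes on ammonia were higher in 5 and lower in 10 of 16 cases [5 higher, 11 lower] (adjusted p = 0.00406, and adjusted p = 0.321 with an estimated correlation), with purA at -3.70 and purH at -3.54. With TMM scaling 1 was higher and 11 were lower. Pyrimidine synthesis genes on ammonia were higher in 2 and lower in 7 of 10 cases (adjusted p = 0.00436, and adjusted p = 0.119 with an estimated correlation; pyrB -4.55). On glutamine, cytidine and cytosine 6, 4 and 0 purine genes were higher and 7, 8 and 15 lower (adjusted p = 0.255, 0.0378 and 3.54e-04, and adjusted p = 0.692, 0.475 and 0.218 with an estimated correlation), and 5, 2 and 0 pyrimidine genes higher and 4, 6 and 8 lower (adjusted p = 0.941, 0.0153 and 0.00633, and adjusted p = 0.962, 0.174 and 0.134 with an estimated correlation). The purine list on cytidine was not called with genes of at least 300 nt (adjusted p = 0.0590; 0.00574 to 0.475 over the alternatives). With TMM scaling the pyrimidine genes on glutamine were 3 higher and 4 lower, and their median of 0.28 and mean of 0.06 lay above 0 while the test pointed down. Calls numbered 2808 on ammonia (1701 higher, 1107 lower, with TMM scaling 1344 and 1324) and 2762 on glutamine (1617 and 1145, with TMM scaling 1325 and 1366). They numbered 2737 on cytidine (1698 and 1039, with TMM scaling 1274 and 1345) and 2526 on cytosine (506 and 2020, with TMM scaling 1176 and 1342).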

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

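The tests on the lopsided calls, on the flagella list and on genes from 150 to under 300 nt, and the division of the gene-length explanation by strain, were chosen only after the results were seen. Listed here are counts, described lists and named genes for which the response of a deletion strain differed from that of WT by the interaction test. An offset between the strains' libraries that differs between sources does not cancel in this test. This selection was revised once after its first result had been seen.

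For Δnac, 678, 567 and 1086 genes differed on glutamine, cytidine and cytosine. Nac-activated genes were lower in 16, 16 and 16 cases, with ydcS at log2 -4.89, -3.74 and -3.76 and ydcT at -4.26, -3.22 and -3.28. Assimilation and Nac-repressed genes were higher in 5, 5 and 4 cases, with asnA at 5.49, 5.50 and 5.24 and serA at 4.12, 2.93 and 2.33. On cytosine that list missed the threshold with an estimated correlation (adjusted p = 0.107). Ast genes were higher in 5, 5 and 5 cases, with astA at 2.19, 1.87 and 2.53. Against WT, 5 were lower in Δnac on ammonia, a level that enters all 3 counts, and 5 were higher on cytosine. Flagellar genes were lower in 49, 49 and 50 cases, with fliC at -3.45, -5.71 and -5.73, and the Δnac ammonia libraries enter all 3 counts. Iron uptake genes were higher in 30 cases on glutamine (entF 3.12) and lower in 14 on cytidine (cirA -1.62). The glnA value was 0.31 on glutamine, and on cytosine glnA was at 0.57, glnG at 0.58 and rutA at 0.71. With TMM scaling glnA on glutamine and rutA on cytosine were not called (adjusted p = 0.189 and 0.116), nor were they without 7 and 5, respectively, of the 8 libraries left out in turn.

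For ΔntrC, 861, 944 and 2306 genes differed. NtrC targets, the deleted gene glnG among them, were lower in 35, 34 and 34 cases, with amtB at -7.36, -6.78 and -6.54 and ddpA at -7.15, -6.44 and -5.78. Rut genes were lower in 7, 7 and 7 cases, with rutA at -9.41, -11.48 and -12.66. Ast genes were lower in 5, 5 and 5 cases, with astA at -4.94, -5.40 and -4.06. Nac-activated genes were lower in 16, 15 and 16 cases, with ydcS at -5.56, -4.43 and -4.49. The response of PhoP-dependent genes, a list that rose in both strains, was lower in 7, 8 and 8 cases, with mgtA at -1.70, -1.42 and -2.11. The serA value was 3.91 on glutamine, and on cytidine cusC was at 5.59, cusF at 5.52, cusB at 4.62 and zinT at -10.81. The glnA values were -2.49 on glutamine and -1.90 on cytidine.

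Of the 2306 genes whose response to cytosine differed in ΔntrC, 2184 or 94.7% were lower. A few transcripts taking a larger part of the TPM total may account for this direction. Without the 10 most abundant genes, 1194 genes were called, 694 higher and 500 lower, so that 41.9% were lower. Why ssrS was high in these libraries was not tested, and an effect of the deletion on these transcripts stays open.

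Flagellar genes were high in Δnac on ammonia, with a list median of 3.93 log2 over WT. A constant offset between the WT and deletion-strain libraries is argued against, since this median exceeded the highest of the other 3 sources by 3.42. A single aberrant library is argued against too, since the lower of the 2 libraries exceeded the highest of the other 22 by 3.63 in the list's mean. A difference between the cultures that both libraries share, and an effect of the deletion on ammonia, stay open and may each account for it.

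Tested genes under 150 nt lay below genes of 300 nt or more by log2 differences of medians of -3.94, -4.11, -4.22 and -4.21 in Δnac against WT, and -2.62, -3.14, -2.37 and -2.25 in ΔntrC, on ammonia, glutamine, cytidine and cytosine. Recovery that falls with gene length may account for the Δnac values, but is argued against in ΔntrC. There genes from 150 to under 300 nt lay above longer ones by up to 0.83 (95% interval from resampling genes, 0.71 to 1.06). A loss limited to genes under 150 nt stays open in ΔntrC. Genes and not libraries were resampled, so the intervals in this paragraph leave out the spread between libraries. An offset shared by both deletion strains cancels in their difference, which tests it only as the sole cause. A shared offset along with a difference between the strains stays open. As the sole cause, a shared offset is argued against for genes from 150 to under 300 nt. Their median difference of ΔntrC from Δnac exceeded that of genes of 300 nt or more by at least 1.42 (1.28 to 1.70). For genes under 150 nt the largest such excess over genes of 300 nt or more, 1.86 on cytosine, met the bound set beforehand against a shared offset, but with median reads of 0 to 1 in Δnac and 2 to 3 in ΔntrC over 2 libraries it cannot be told apart from one, a limit on reads that was set after the value was seen. An effect of the deletions on short transcripts was not tested and is confounded with the possible batch.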

How the results depend on the processing

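Alternatives on genes of at least 300 nt, with voom and without the deletion-strain cytosine libraries were chosen after seeing the data. Of 32 counts, 30 stayed within 1.5 times under each alternative run. The exceptions were the genes whose response to cytosine differed between ΔntrC and WT and the gene list tests. The former fell from 2306 to 1134 with TMM scaling, 1176 with quantile normalization, 1194 without the 10 most abundant genes, 1142 with voom and 1208 with genes of at least 300 nt. The latter fell from 335 to 124 with an estimated correlation. Of 323 values of named genes, 300 kept direction and side of the threshold under each alternative, as did 119 of 170 list results.

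For glnA, the difference between the ΔntrC and WT responses to cytosine turned from -0.24 to 0.50 with TMM scaling, 0.60 without the 10 most abundant genes, 0.47 with voom and 0.65 with genes of at least 300 nt. Between Δnac and WT, glnA turned from -0.36 to 0.12 on glutamine and from -0.09 to 0.39 on cytosine with quantile normalization. The cause was not tested in these cases. The call of rutA (ΔntrC, cytosine against ammonia) ended with TMM scaling, quantile normalization, pseudocount 10, the libraries of 1 genotype, voom, genes of at least 300 nt and without the 10 most abundant genes (adjusted p = 0.0117 to 0.913 over the alternatives). The call of rutA (Δnac minus WT, cytosine) ended with TMM scaling, quantile normalization, no trend or robust options, pseudocount 0.1, voom and genes of at least 300 nt (adjusted p = 0.00338 to 0.323 over the alternatives). That of glnA (Δnac minus WT, glutamine) ended with TMM scaling and no trend or robust options (adjusted p = 3.29e-04 to 0.189). That of ssuA (WT, cytosine) ended with quantile normalization, pseudocount 0.1 and voom (adjusted p = 0.0160 to 0.248). Single alternatives ended the calls of rutA (WT, cytosine against cytidine; pseudocount 0.1, adjusted p = 0.226), rutG (the same comparison, libraries of 1 genotype, 0.0627), gadE (cytidine, voom, 0.250 in WT and 0.0872 in ΔntrC) and glnA (Δnac against WT, cytidine, quantile normalization, 0.368). Calls were gained under some alternatives for nac (WT, cytosine against cytidine), serA (Δnac, glutamine), glnG (Δnac minus WT, glutamine) and glnA (ΔntrC on cytidine, Δnac against WT on cytosine, and the differences from WT of Δnac on cytidine and ΔntrC on cytosine). Leaving out each library in turn, with the lone sample assumed to vary like the other groups, moved no count by over 1.5 times. The largest relative fall was for ΔntrC on cytidine against ammonia, from 1194 to 798. Among named genes 39 of the values so obtained lost their call, and 6 gained one. The losses were for codA, codB (WT, glutamine), gadE and ugpC (WT, cytidine), phoB and ssuA (WT, cytosine), rutA and rutG (WT, cytosine against cytidine), rutA (ΔntrC, cytosine) and, for Δnac minus WT, glnA on glutamine and rutA on cytosine.

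Replicate numbers did not pair the samples: differences between replicates correlated at -0.07 to 0.10 over 66 pairs of groups, with 1 over the limit of 0.1. With a replicate block, counts were 0.903 to 1.01 times those without it, for example 1995 in place of 1997 genes for WT on glutamine. Under the block the adjusted p was 0.0553 for ssuA (WT, cytosine) and 0.0572 for glnA (Δnac minus WT, glutamine), and no other call of a named gene changed. Among lists the call of heat shock genes (Δnac against WT, glutamine) ended with the block (adjusted p = 0.0606). Few reads limit what is known of short and rare transcripts. Median reads over 2 libraries were 0 to 31 for genes under 150 nt, against 209 to 566 for genes of 300 nt or more. A gene at 0 reads bounds a fold only by its floor. In the simulation of WT on glutamine, 59.3% of the genes called on the TPM scale over 20 draws were unchanged ones, 12 to 2497 genes per draw. With TMM scaling 7.91% were, 8 to 25 per draw.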

Other observations

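Gene groups named here were chosen after their values were seen, so their counts are descriptions and not tests of a group. The zinc uptake genes zinT, znuA, znuB and znuC and the ribosomal protein paralogue gene ykgM were all called higher in WT on cytidine, at log2 2.52 to 9.56 against ammonia. On glutamine the 5 genes lay between -0.29 and 0.35, and on cytosine between -0.17 and 0.07. The zinT transcript stood at 4290.3 ± 139 TPM (SD, n = 2) in WT on cytidine, and at 4.72, 6.23 and 4.97 TPM on ammonia, glutamine and cytosine. The response of all 5 to cytidine was lower in Δnac and in ΔntrC than in WT by the interaction test, with medians of -5.90 and -5.26. Within Δnac they lay between -1.26 and -0.07 on cytidine against ammonia, with 0 called higher and 1 lower (2 lower with TMM scaling). Within ΔntrC they lay between -1.25 and 1.05, with 1 called higher and 0 lower. An offset limited to the WT cytidine libraries would not cancel in this test and cannot be told apart from strain. Of 8 copper response genes of the Cus and Cue systems, 8 were lower in WT on glutamine and on cytosine than on ammonia, and on cytidine 6 were lower and 2 higher. In Δnac 8 were lower on each of the 3 sources. In ΔntrC 8, 6 and 8 were lower on glutamine, cytidine and cytosine, and with TMM scaling 5 on cytosine. Their median on cytidine was -0.62 in ΔntrC and -3.07 in WT.

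A group of 17 genes covered colanic acid, a capsule polysaccharide, with the regulator gene rcsA among them. In ΔntrC 16 were higher than in WT on ammonia, with a median log2 of 4.55. On glutamine 15 and on cytidine 16 were higher. On cytosine 12 were lower, and with TMM scaling 9. Against Δnac on ammonia, 17 were higher in ΔntrC, with a median of 4.21. On glutamine and cytidine 15 and 16 were higher than in Δnac, and on cytosine 1 was higher and 8 lower (with TMM scaling 2 and 7). In WT, 13 rose on cytosine relative to ammonia. Within ΔntrC, 15 fell on glutamine, 7 on cytidine and 17 on cytosine relative to ammonia, with medians of -1.31, -0.82 and -4.30. With TMM scaling 15, 7 and 17 fell.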
